A study of Mus musculus with 84 samples.

How the data were processed

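Sequenced were 84 liver libraries labelled as from pregnant mice of 14 strains, 3 with TCDD and 3 with vehicle in each, dosed at 0.1 µg/kg on 10 days, per the labels. Mice were 6 to 8 weeks old at the start, RNA had an integrity number of at least 7, and libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols; that kit does not mark strand. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, trimmed with Trimmomatic 0.38, aligned with Bowtie2 2.3.2.25 and assigned to genes with HTSeq 0.6.1, and DESeq2, given as version 3.8, was used for testing. The notes name the genome build mm9; the names of the deposited files point to references that differ between strains, which the notes do not describe. No coordinates are given, because the reference at hand is of another build.

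The deposited files are 84 tables of whole-number counts per gene and a table of the authors' log2 fold changes and p-values per strain, per the file headers. The count files hold 37310 gene IDs, of which 32620 were named from a reference table, 2059 from the authors' table and 2631 not at all. Counts assigned to genes ran from 9122410 to 19689600 per library. A further 46.7% to 52.6% of reads fell in no gene, 0.442% to 1.41% were ambiguous between genes, and reads with more than 1 alignment were 3.74% to 4.35% in the 18 BXD libraries and 7.80% to 10.2% in the other 66. Pairs of libraries of a group differed by 13.6 to 223 times what counting error alone gives (chi-square per degree of freedom).

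Tests were run in R 4.3.3 with edgeR 4.0.16: TMM scaling (factors 0.775 to 1.16), the filterByExpr filter, which kept 16195 genes, and the robust quasi-likelihood fit on 28 groups, so that all libraries share the estimate of spread (common dispersion 0.0651). Contrasts were the mean of the 14 within-strain TCDD effects, each strain's effect, the strain by treatment interaction on 13 contrasts together, each strain against the other 13, and the vehicle groups. Benjamini-Hochberg adjusted p below 0.05 within a contrast is a call. SEs are those of the fitted log2 changes. CPM divide by the total gene counts of the library, without the TMM factors. The log2 CPM behind the variance shares, the levels of Ahr, the spread within groups and the deviations of the clock genes use TMM-scaled totals and a prior count of 1. A few counts are rounded to 2 digits and written as 1.8e+02. Replicate numbers follow only the order of the accessions and pair nothing.

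Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 30 lists (504 memberships), and over 420 tests of strain and list. Muscle and adrenal cortex marker lists, the Y-linked genes and the tests of the libraries that stood apart were chosen after the counts were seen. Relations across strains used Pearson and Spearman correlation with 100000 permutations, two-sided, adjusted over 5 relations. Where strains fell into clusters, only the values within a cluster of at least 6 are given.

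The contrasts, lists, relations, most alternatives and the rule for genes named in the text were fixed before the data were examined. The rule names: for the average, the 15 largest rises and falls among calls with the same sign in at least 12 strains; all measured genes of the AHR battery and AHR complex; the 12 smallest p-values of the strain by treatment test; per strain the 2 largest rises and falls among calls with at least 1 CPM outside the AHR battery; per strain against the other 13 the 2 smallest p-values; and per list the 3 members with the smallest p. Predicted genes, Riken clones, pseudogenes and small RNAs were passed over, and a few genes that the rule names are not used here.

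Alternatives were DESeq2 1.42.0 on the same design, median-ratio size factors, no low-count filter (26400 genes), dispersion without robust estimation, each strain fitted alone, an additive model, leaving out each library or strain, leaving out the BXD lines and CC019/TauUnc, and a threshold of 0.01 for shared calls. Added later were fits without the library labelled C57BL6/J TCDD replicate 3, without it, A/J vehicle replicate 2 and BXD-40/TyJ vehicle replicate 1, and with trends on GC content and gene length (splines of 4 degrees of freedom per library, for the 15515 genes, 95.8%, with a value) taken out as offsets.

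Simulated counts with a seeded set of genes changed by known folds tested the average contrast, the effect in NOD/SHILTJ, the strain by treatment test, NOD/SHILTJ against the other 13 and the list tests of the average. The relations, the vehicle differences and the additive model were not simulated. Counts were drawn with the fitted trend of dispersion and 1 mean per gene and strain, so no simulated library stood apart. For the average the fold was the same in all strains. The rates below hold for such counts only. In the real data, other draws of the treatment labels within strains gave up to 1490 calls for the average. For the average contrast (16042 genes) 92.5% of genes changed 1.5-fold and 98.5% of those changed 4-fold were called, with 4.41% false calls. For NOD/SHILTJ alone among the 14 strains 4.48%, 41.8% and 80.3% were called at folds of 1.5, 2 and 4, with 6.29% false calls. For the strain by treatment test 0%, 5.97% and 65.2% were called, with 7.84% false calls. For NOD/SHILTJ against the other 13 it was 4.48%, 34.3% and 78.8%, with 3.70% false calls. For NOD/SHILTJ fitted on its own libraries (14119 genes) 8.47%, 50.8% and 90.2% were called.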

Results

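RNA sequencing was deposited for 84 liver libraries labelled as coming from pregnant female mice of 14 strains. In each strain 3 libraries are labelled as treated with TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin), a long-lived ligand of the aryl hydrocarbon receptor (AHR), at 0.1 µg/kg by mouth on each of 10 days. A further 3 libraries of each strain are labelled as given the peanut butter vehicle alone. The strains were A/J, C57BL6/J, CBA/J, DBA1/J, FVB/NJ, C3HeB/FeJ, BALB/CJ, NZO/HILTJ, NOD/SHILTJ and 129S1/SVIMJ, the recombinant inbred lines BXD100/RwwJ, BXD91/2RwwJ and BXD-40/TyJ, and the Collaborative Cross line CC019/TauUnc. Counts assigned to genes ranged from 9122410 in the library labelled C57BL6/J TCDD replicate 3 to 19689600, with a median of 16202900 per library, and 16195 genes were tested. Differences between strains held 51.5% of the variance of log2 CPM (counts scaled to the TMM-scaled total of each library) and treatment held 0.769%. These shares are not adjusted for the number of groups, 14 and 2. More groups hold more variance by chance, so the 2 shares are not directly comparable. The labels describe treated mice without stating that each library came from its own mouse, so p-values measure the spread between these libraries.

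The average comparison asked what the dose did to the liver over all strains. Known AHR targets were among the rises. Cyp1a1 (ENSMUSG00000032315.5), which encodes a cytochrome P450 that oxidises aromatic hydrocarbons, rose by 5.08 ± 0.31 on the log2 scale (mean of the 14 within-strain changes ± SE, 84 libraries) and was higher in 12 strains. Its neighbour Cyp1a2 (ENSMUSG00000032310.3), the form abundant in normal liver, rose by 2.29 ± 0.12, and the AHR target Htatip2 (ENSMUSG00000039745.7) by 0.70 ± 0.06, each in 14 of 14 strains. Nptx1 (ENSMUSG00000025582.4), which encodes a secreted neuronal pentraxin, rose by 1.67 ± 0.21 in 12 strains. The quasi-likelihood test of edgeR gave adjusted p-values of 4.3e-19 for Cyp1a1, 9.0e-23 for Cyp1a2, 2.6e-12 for Htatip2 and 3.4e-07 for Nptx1. Of the 29 genes called, 25 rose and 4 fell; 962 genes had an unadjusted p below 0.05, and DESeq2 called 42. Without the 3 BXD lines and CC019/TauUnc 5 genes were called, and 9 without BXD91/2RwwJ, 16 without CBA/J and 17 without BXD100/RwwJ.

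Other genes rose as well. Abcc3, which encodes an exporter of conjugated bile acids and drugs, rose by 0.40 ± 0.08 (adjusted p = 0.00925, edgeR) in 13 strains. The glutathione transferase gene Gstm1 rose by 0.30 ± 0.06 (0.00682), the sulfotransferase gene Sult5a1 by 0.58 ± 0.10 (5.0e-04), the cytochrome b5 gene Cyb5a by 0.28 ± 0.04 (1.6e-05) and the P450 gene Cyp2c37 by 0.33 ± 0.07 (0.0240), each in 12 strains. Gstm4 (0.29 ± 0.07, 13 strains) and the glucuronosyltransferase gene Ugt1a6a (0.20 ± 0.05, 12 strains) both had an adjusted p of 0.0480. Leaving out any of 60 single libraries ended the call of Gstm4, and any of 66 that of Ugt1a6a. Members of the Gstm, Cyp2c and Ugt1a families share sequence, so their reads may be divided uncertainly. Pcp4l1 rose by 0.57 ± 0.12 (0.0203), Pmm1, of mannose metabolism, by 0.40 ± 0.09 (0.0203), and the ubiquitin ligase gene Neurl3 by 0.42 ± 0.09 (0.0183). Hectd2os, antisense to Hectd2, rose by 0.86 ± 0.19 (0.0203); the kit did not mark strand, so its reads cannot be told from those of Hectd2. The falls among genes with 1 sign in at least 12 strains were the plasma protein genes Hp (haptoglobin, −0.36 ± 0.08, 0.0199) and C8a (complement, −0.33 ± 0.07, 0.0203, lower in 14 strains) and the growth factor gene Fgf1 (−0.24 ± 0.06, 0.0349), whose call ended without any of 25 single libraries. Chosen after the values were seen, the other fall was Calml4 (−0.62 ± 0.14, 0.0244), and Slc46a3 rose by 0.52 ± 0.08 (1.9e-05) in 11 strains.

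**Figure D1:**
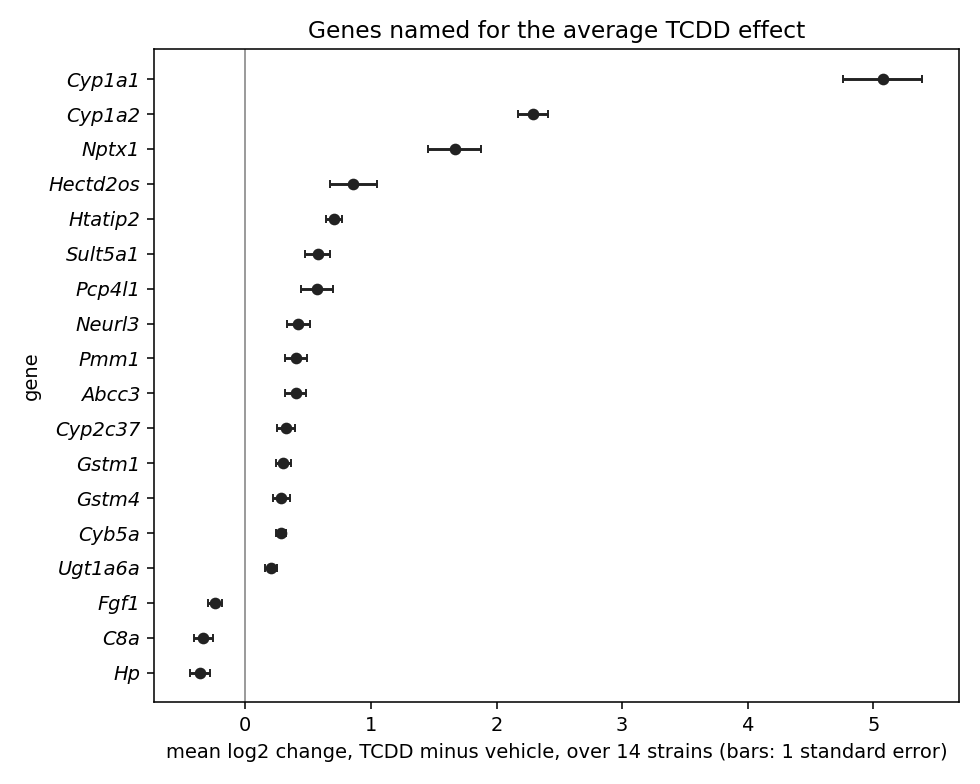
Mean log2 change over the 14 strains (TCDD against vehicle, horizontal axis) of the 18 genes that were called for the average and had the same sign in at least 12 strains; bars are 1 SE. Cyp1a1 at 5.08 and Cyp1a2 at 2.29 lie farthest to the right, and Hp at −0.36 farthest to the left.

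Among 30 gene lists, 7 were called in the average, a number that 11 of 25 splits of the libraries, the real one included, reached. The AHR battery rose, with 12 of 13 measured genes positive, 4 called over all genes (Cyp1a1, Cyp1a2, Htatip2 and Ugt1a6a) and 7 when adjusted over the list alone. Counted as positive was Gsta1, whose change of 0.64 had an SE of 1705, so that its sign carries no information. The NRF2 and glutathione genes rose, with 19 of 23 positive, 2 called over all genes and 9 called higher and 1 lower when adjusted over the list alone. The acute phase genes fell, with 1 of 24 positive, a median log2 change of −0.16, 1 gene (Hp) called over all genes and 13 when adjusted over the list alone. Camera gave adjusted p = 3.4e-51 for the AHR battery (1.5e-14 with an estimated correlation), 1.7e-10 for the NRF2 list (0.0208) and 6.4e-20 for the acute phase list (0.0331). The CAR and PXR targets (18 of 23 positive, 1 called, 6 when adjusted over the list alone) and the bile acid genes (19 of 22 positive, 1 called, 1 when adjusted over the list alone) were called higher with the preset correlation only. Their adjusted p were 1.3e-05 and 0.00289, and 0.0881 and 0.120 with an estimated correlation. The interferon response genes (4 of 24 positive, 0 called either way) and the circadian clock genes (4 of 19 positive) were called lower with the preset correlation only. Their adjusted p were 8.4e-05 and 0.01, and 0.547 and 0.17 with an estimated correlation.

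Single members of those lists stayed short of the threshold over all genes in edgeR. In the AHR battery these included Nqo1 (0.28 ± 0.08, adjusted p = 0.157), which encodes a quinone reductase, Nfe2l2, the gene of NRF2 itself (0.19 ± 0.06, 0.264), Ugdh (0.21 ± 0.06, 0.281), Cyp1b1 (0.38 ± 0.27, 0.918) and the AHR feedback gene Tiparp (−0.13 ± 0.12, 0.956). Xdh, Ugt1a7c, Ugt1a6b and Gsta1 had adjusted p-values of 0.980 or more. Gstm3 (0.47 ± 0.11, 0.0653) came closest among the glutathione genes. In the acute phase list Saa4 (−0.28 ± 0.07, 0.0760) and Orm2 (−0.66 ± 0.17, 0.0761) came closest. Abcg8 (0.743) and Hsd3b7 (0.749) of the bile acid list, Cyp2c29 (0.184) and Cyp2c50 (0.220) of the CAR and PXR list, Mx2 (0.579), Stat2 (0.667) and Rtp4 (0.802) of the interferon list, and Cry1 (0.579) and Bhlhe40 (0.609) of the clock list were not called. The receptor genes themselves did not pass, with Ahr at 0.0072 ± 0.09, Arnt at −0.08 ± 0.04 (0.864) and the chaperone gene Hsp90aa1 at −0.15 ± 0.15 (0.959); Hsp90ab1 and Ptges3 both had an adjusted p of 1.00.

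The other 23 lists were not called in the average. For lipid and glucose metabolism the camera adjusted p was 0.707 for fatty acid synthesis (leading gene Elovl5, 0.19 ± 0.05), 0.338 for PPARA targets (Ehhadh, 0.20 ± 0.08), 0.780 each for cholesterol synthesis and lipid uptake, and 0.832 for glucose metabolism (Pklr, −0.18 ± 0.07). For retinoid metabolism it was 0.324, with the retinoic acid hydroxylase gene Cyp26a1 at 0.64 ± 0.19 (gene adjusted p = 0.264, edgeR). Heme synthesis had 0.121, iron handling 0.262, ER stress 0.324, p53 targets 0.780, cell cycle 0.747 and the AHR complex 0.506. Among cell markers, lymphocytes had 0.155, neutrophils 0.208, Kupffer cells 0.210, sinusoidal endothelium 0.365, cholangiocytes 0.400, pancreas acinar cells 0.400, erythroid cells 0.709, adipose 0.780 and stellate cells 0.925. The median of the adipose list was −0.15 and its mean −0.39 while the test pointed up; for stellate cells the median was −0.0088 and the mean 0.02, the test pointing up. The median of the glucose list was −0.01 and its mean 0.0084, the test pointing down. Male-biased genes had 0.245 (Gstp1, 0.26 ± 0.07, gene adjusted p = 0.11) and female-biased genes 0.780. Without the library labelled C57BL6/J TCDD replicate 3 the female-biased list was called higher with the preset correlation only (0.00772, and 0.580 with an estimated correlation). Without that library, A/J vehicle replicate 2 and BXD-40/TyJ vehicle replicate 1 the Kupffer (0.0267, 0.667) and lymphocyte (0.0415, 0.488) lists were called lower, again with the preset correlation only.

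The next comparison asked whether the response depended on the strain. Cyp1a1 did: mean CPM under TCDD (± SD, n = 3) reached 1679 ± 212 in BXD91/2RwwJ, 1461 ± 175.7 in CBA/J and 1338 ± 136.7 in BXD100/RwwJ, against 0.0593 to 2.43 over the 42 vehicle libraries. C57BL6/J had 999 ± 871, made of 1604 and 1393 CPM in 2 libraries and 1.21 CPM in the library labelled TCDD replicate 3, and C3HeB/FeJ had 505 ± 620 with a range of 75.9 to 1217. Lower levels were measured in FVB/NJ (26 ± 11.5), BALB/CJ (20.7 ± 9.15), A/J (10.4 ± 6.86) and DBA1/J (9.29 ± 6.05). In 129S1/SVIMJ (3.33 ± 1.69) and BXD-40/TyJ (2.08 ± 0.601) the mean stood 3.64 and 2.58 times above vehicle. In NZO/HILTJ (0.875 ± 0.472), CC019/TauUnc (0.674 ± 0.430) and NOD/SHILTJ (0.631 ± 0.0363) Cyp1a1 was 0.806, 0.872 and 1.26 times the vehicle mean. The strain by treatment test of edgeR gave Cyp1a1 an adjusted p of 8.7e-11.

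Cyp1a2 followed a like order from a much higher baseline of 403 to 745 CPM. Its ratio of TCDD to vehicle mean was 17.2 in BXD91/2RwwJ, 15.4 in BXD100/RwwJ, 12.3 in CBA/J, 12.0 in C3HeB/FeJ and 10.3 in C57BL6/J. The 10.3 of C57BL6/J includes the library labelled TCDD replicate 3 at 479 CPM; without it the mean was 8294 CPM against 551.8 in vehicle, so the place of C57BL6/J in this order depends on that library. The ratio was 7.2 in A/J, 5.85 in BALB/CJ, 5.23 in FVB/NJ, 3.03 in DBA1/J, 2.94 in BXD-40/TyJ and 2.60 in 129S1/SVIMJ. In 129S1/SVIMJ the TCDD libraries ran from 599 to 2095 CPM around a mean of 1101 (SD 860), so that ratio rests largely on the highest library. The ratio was 1.38 in NOD/SHILTJ, 1.24 in CC019/TauUnc and 1.21 in NZO/HILTJ. The log2 changes there, of 0.60 ± 0.43, 0.31 ± 0.43 and 0.29 ± 0.43, were not called. The strain by treatment test of edgeR gave an adjusted p of 3.4e-06.

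**Figure D2:**
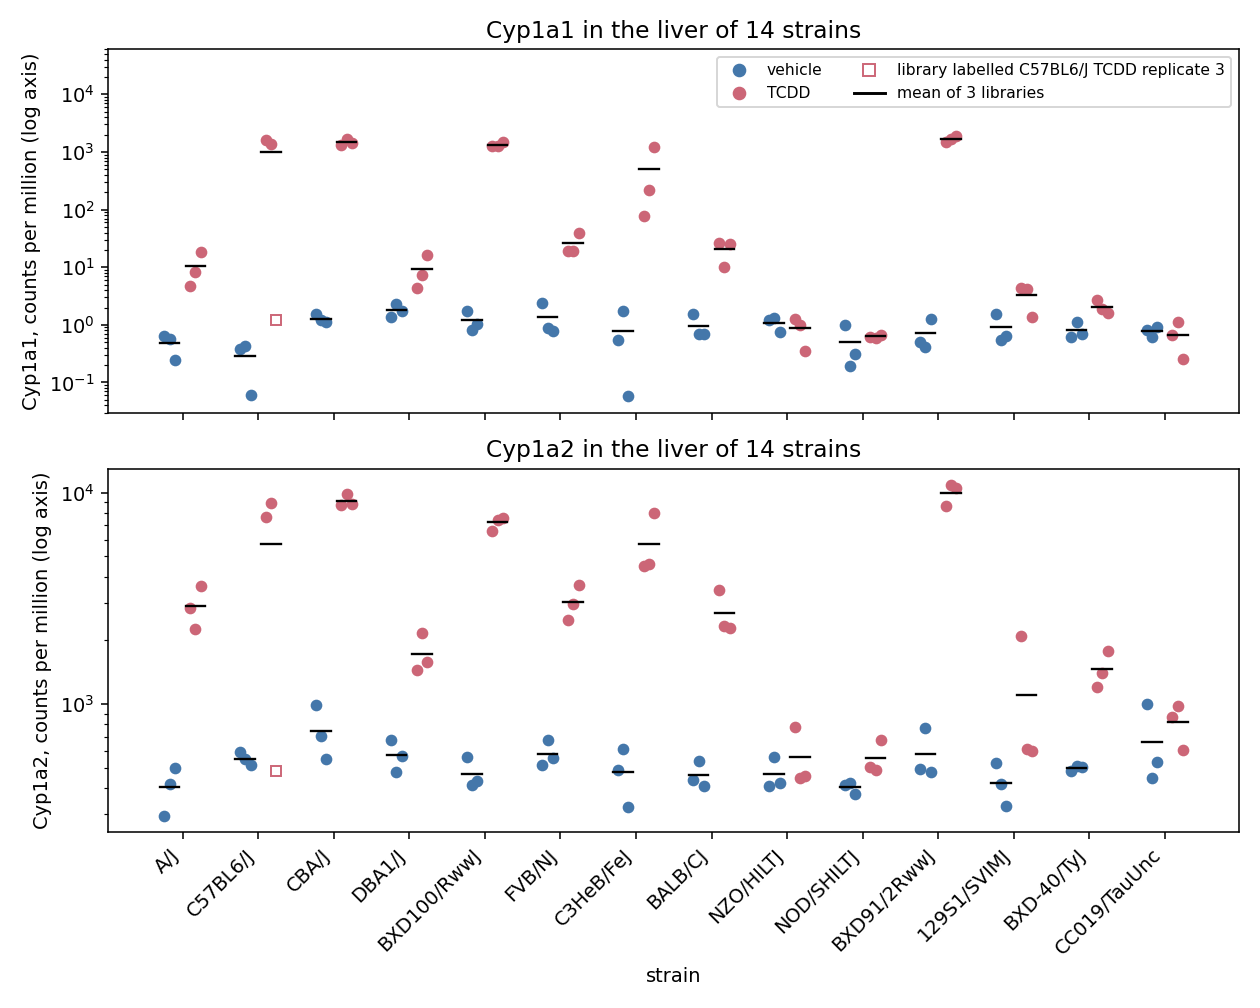
CPM (log axis) of Cyp1a1 and Cyp1a2 in each library by strain, vehicle in blue and TCDD in red, with a black line at the mean of 3; the open square is the library labelled C57BL6/J TCDD replicate 3. Cyp1a1 under TCDD averaged 1679 in BXD91/2RwwJ and 0.631 in NOD/SHILTJ.

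In the same test 3 other genes depended on strain. Slc46a3 (ENSMUSG00000029650.4), which encodes a lysosomal transporter, rose from 43.2 to 175.8 ± 17.5 CPM in BXD91/2RwwJ (log2 2.04 ± 0.30, adjusted p = 2.3e-05) and by 1.60 ± 0.29 in BXD100/RwwJ (0.00401), while in 129S1/SVIMJ it stood at −0.66 ± 0.29, a change not called. Nptx1 rose by 4.17 ± 0.88 in C57BL6/J (0.0125), 4.14 ± 0.79 in BXD91/2RwwJ (0.00635), 4.04 ± 0.78 in BXD100/RwwJ (0.00775) and 3.75 ± 0.76 in C3HeB/FeJ (0.0265). Gstp1, which encodes a glutathione transferase more abundant in male liver, rose by 1.45 ± 0.26 in C57BL6/J (0.00138). The adjusted p of the strain by treatment test in edgeR was 8.2e-04 for Slc46a3, 0.0126 for Nptx1 and 0.0337 for Gstp1. Without the library labelled C57BL6/J TCDD replicate 3 it was 0.0831 for Gstp1, whose rise in C57BL6/J was then 1.16 (0.0920). The strain dependence of Gstp1 ended without any of 28 single libraries. Mup20 (0.0640), Cyfip2 (0.0645), Ppp1cc (0.0771), Htatip2 (0.0771), Sh2d3c (0.0999), Sel1l3 (0.111) and Mrpl48 (0.119) fell short, and Htatip2 passed (8.6e-04) without that library. In total 5 genes were called, 1381 had an unadjusted p below 0.05 and DESeq2 called 166. The count was 11 without the library labelled C57BL6/J TCDD replicate 3, 14 without the 3 libraries named above, 16 without A/J vehicle replicate 1, 15 with trends on GC content and gene length taken out, and 1 without the BXD lines and CC019/TauUnc.

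C57BL6/J held a library that stood apart from its group. The library labelled TCDD replicate 3 had 0.219 CPM of Xist, the transcript of the inactive X chromosome, against 103.5 to 435 in the other C57BL6/J libraries, and 128.5 CPM over 4 Y-linked genes, against at most 0.0691 in any other library. It also carried the genes of male liver: Mup20, a major urinary protein, stood at 705 CPM against at most 26.2 elsewhere, and the male-biased genes summed to 4104 CPM against 522 to 1056 in its strain. Of the genes called in C57BL6/J, 57 rose and 8 fell. The largest rises outside the AHR battery were Cyp4a12a and Cyp4a12b, P450 genes of male liver; Cyp4a12a had 0 counts in the 3 vehicle libraries and at most 28.6 CPM under TCDD. Orm2 and Orm1, acute phase genes that share sequence, fell by 2.69 ± 0.66 and 1.02 ± 0.23 (adjusted p 0.0386 and 0.0292, edgeR), calls that ended without that library (changes of −2.26 and −0.79, both 0.564). The female-biased list was lower, with 0 of 19 genes positive (adjusted p = 1.5e-18, camera, and 0.0410 with an estimated correlation). Without that library 10 genes were called, 5 of them among the 65; Mup20 then changed by 1.49 (adjusted p = 1), against 6.64 ± 0.97 (2.9e-05) with it. Cyp1a1 then rose by 12.27 ± 0.90 and Cyp1a2 by 3.90 ± 0.39. The count also moved to 7, 123 and 8 without vehicle replicates 1, 2 and 3, to 1.4e+02 without TCDD replicate 1 and to 552 without TCDD replicate 2; DESeq2 called 1.8e+02.

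Falling calls in A/J and BXD-40/TyJ were muscle and adrenal genes that stood high in 1 vehicle library each. A/J vehicle replicate 2 held 3120 CPM of skeletal muscle markers, 522 of adrenal cortex markers and 458 of pancreas acinar markers, against 8.02 and 8.37 CPM of muscle markers in the other A/J vehicle libraries. BXD-40/TyJ vehicle replicate 1 held 713 CPM of adrenal markers, against 3.58 to 61.1 in the other 82 libraries. In A/J 80 genes were called, 6 higher and 74 lower, the largest falls being the muscle genes Ttn (−11.43 ± 2.48, adjusted p = 0.0140, edgeR) and Mybpc1, which had 0 counts under TCDD. In BXD-40/TyJ 26 genes rose and 12 fell, led by the steroid synthesis genes Cyp21a1 (−9.83 ± 1.99, 0.0167) and Star (−5.38 ± 1.01, 0.0146) and, among the rises, by Fcgbp (5.14 ± 1.22, 0.0425) and Myo15b (3.86 ± 0.78, 0.0151). Without these libraries and the library labelled C57BL6/J TCDD replicate 3, Star changed by 0.33 and Cyp21a1 by 0.29, and BXD-40/TyJ had 0 calls; it also had 0 without TCDD replicate 3, 1 without TCDD replicate 1, 20 without vehicle replicate 3 and 72 without TCDD replicate 2. With all libraries 1986 genes of BXD-40/TyJ had an unadjusted p below 0.05 and DESeq2 called 89. In this strain the slope of gene level on GC content ran with the treatment. It was −0.131 to −0.0581 in the vehicle libraries and 0.0711 to 0.142 in the TCDD libraries. Rising genes had a median GC content of 56.1%, falling genes 45.9% and genes not called 49.9%. With trends on GC content and length taken out 21 genes were called, 13 of them higher. Whether these trends come from the libraries or the livers cannot be told apart.

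In A/J the list of CAR and PXR targets was higher and the list of interferon genes lower. The P450 gene Cyp3a59 rose by 2.22 ± 0.54 (adjusted p = 0.0322, edgeR) and Sult5a1 by 1.71 ± 0.36 (0.0105), and 21 of 23 CAR and PXR targets were positive (median 0.54, camera adjusted p = 2.8e-09, 0.0132 with an estimated correlation), 7 of them called when adjusted over the list alone. All 24 interferon genes were negative (median −0.60, 1.3e-07, and 0.197 with an estimated correlation). Without the 3 libraries A/J had 28 calls, 15 of them among the 80, with 24 falls, chosen after the values were seen, that included the interferon-induced GTPase gene Gbp2 (−2.99 ± 0.48, 3.9e-04). The same falls held Lars2 (−3.50), the small nuclear RNA Rn7sk (−4.55) and predicted genes such as Gm15564 (−5.23), Gm23935 (−4.02) and Gm24187 (−3.96). With all libraries these falls were smaller, at −2.47 for Gbp2, −2.94 for Lars2 and −3.96 for Rn7sk. Whether the falls without the 3 libraries rest on a single remaining A/J vehicle library was not tested. The adjusted p of Cyp3a59 was then 0.157 and that of Sult5a1 0.0277, and of the CAR and PXR list (adjusted p = 6.0e-09, and 0.00317 with an estimated correlation) 0 genes were called when adjusted over the list alone. The interferon list then had an adjusted p of 4.0e-21, and 0.0147 with an estimated correlation. The Kupffer and lymphocyte lists were lower there too, with the preset correlation only. Of the Kupffer genes 1 of 16 was positive (median −0.67, camera adjusted p = 6.7e-07, and 0.22 with an estimated correlation). Of the lymphocyte genes 3 of 15 were positive (median −0.95, 5.2e-04, and 0.141 with an estimated correlation). The count of 80 became 1.6e+02 without vehicle replicate 1, 25 without vehicle replicate 2, and 2, 4 and 9 without TCDD replicates 1, 2 and 3.

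**Figure D3:**
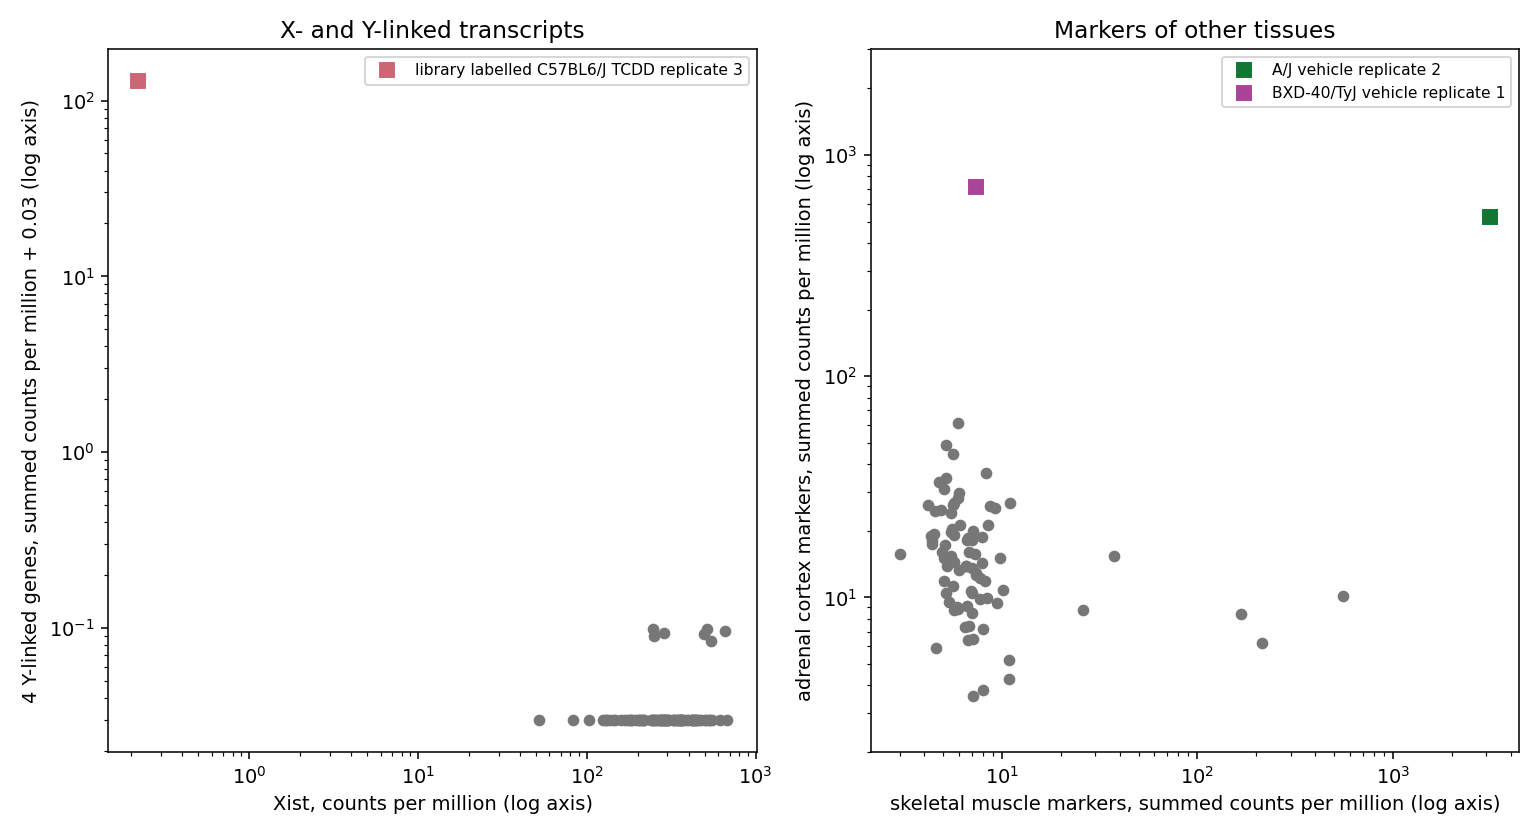
Left, Xist against the sum of 4 Y-linked genes in each library (CPM, log axes); the library labelled C57BL6/J TCDD replicate 3 lies alone at 0.219 and 128.5. Right, sums of skeletal muscle and adrenal cortex markers (CPM, log axes); A/J vehicle replicate 2 lies alone at 3120 and 522, and BXD-40/TyJ vehicle replicate 1 at 713 CPM of adrenal markers.

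NOD/SHILTJ had the most calls and no called change of Cyp1a1. Of 310 called genes 159 rose and the rest fell. The matrix genes Tnxb (−2.29), Fbn1 (−1.92), Col6a3 (−1.80) and Hspg2 (−1.74) were among the falls (adjusted p 0.00774, 0.0371, 0.0378 and 0.0190, edgeR; chosen after their values were seen). By the fixed rule the largest falls were the protease gene Ctse (−3.24 ± 0.89, adjusted p = 0.0398, edgeR, at 0.188 to 5.26 CPM in vehicle) and the secreted WNT regulator Dkk3 (−2.43 ± 0.53, 0.0149). The largest rises were the keratin gene Krt4 (5.58 ± 1.42, 0.0301, at 0.122 to 32.8 CPM under TCDD) and Hamp2 (2.32 ± 0.63, 0.0378). All 13 stellate cell markers were negative, at a median of −1.01 (camera adjusted p = 9.1e-05, and 0.788 with an estimated correlation). Falling genes were long, at a median of 5047 nt against 1691 for rising and 3056 for other genes. Without vehicle replicate 2 the count of 310 fell to 2, without TCDD replicate 2 to 9, without vehicle replicate 3 to 11 and without TCDD replicate 3 to 51, and it was 588 without TCDD replicate 1. It was 166 with trends on GC content and length taken out, 600 without the library labelled C57BL6/J TCDD replicate 3 and 737 by DESeq2.

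Calls in the other strains were AHR targets and few other genes. CBA/J had 4 (Cyp1a1, Cyp1a2, Htatip2 and the glucuronosyltransferase gene Ugt2b35, which rose by 1.09 ± 0.21), BXD100/RwwJ 5 (Cyp1a1, Cyp1a2, Htatip2, Nptx1 and Slc46a3) and C3HeB/FeJ 5 (Cyp1a1, Cyp1a2, Htatip2, Nptx1 and the sorting receptor gene Sorcs3). BXD91/2RwwJ had 9, the same 5 as BXD100/RwwJ with Cyfip2 (1.98), Fbxw9 (0.73), Cyb5a (0.73) and a predicted gene, these chosen after their values were seen. Cyp1a2 was the only call in FVB/NJ (2.39 ± 0.46, adjusted p = 0.0349, edgeR) and in BALB/CJ (2.47 ± 0.46, 0.0191). Each of these calls was higher under TCDD. Cyp1a1 missed the threshold of edgeR in FVB/NJ (4.25, adjusted p = 0.114) and BALB/CJ (4.31, 0.192). Without the 3 libraries that stood apart Cyp1a1 was called in both, at 4.26 in FVB/NJ (2.3e-04) and 4.31 in BALB/CJ (3.6e-04). The AHR battery was called with an estimated correlation in BXD91/2RwwJ (9.8e-11), BXD100/RwwJ (9.7e-09), CBA/J (5.7e-08), C3HeB/FeJ (1.2e-04), C57BL6/J (0.00810) and A/J (0.0132). In BXD91/2RwwJ the NRF2 list was also higher and the erythroid and ER stress lists lower, each at 0.0491 with an estimated correlation. DBA1/J, NZO/HILTJ, 129S1/SVIMJ and CC019/TauUnc had 0 calls in edgeR, with 294, 322, 669 and 722 genes at an unadjusted p below 0.05 and 2, 2, 4 and 4 calls by DESeq2. The count in CBA/J was 2 without vehicle replicate 1 or 2, 28 without vehicle replicate 3 and 10 without TCDD replicate 1. In C3HeB/FeJ it was 706 without TCDD replicate 2 and 2 or 3 without any other library of the strain, in BXD100/RwwJ 2 without vehicle replicate 2 or 3, in BXD91/2RwwJ 5 without vehicle replicate 3, and in 129S1/SVIMJ 8 without TCDD replicate 2. The single calls of FVB/NJ and BALB/CJ ended without 5 and 4 of their 6 libraries, all 3 vehicle libraries among them in each strain.

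**Figure D4:**
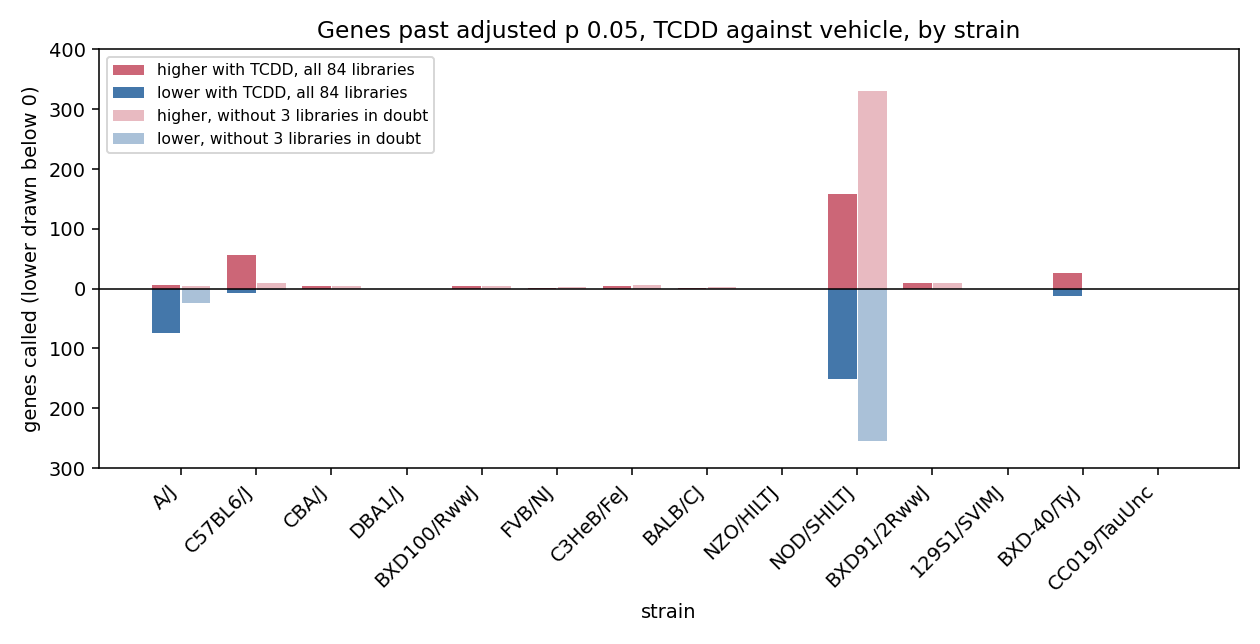
Genes called higher and lower under TCDD in each strain (bars, number of genes), with all 84 libraries and without the 3 libraries that stood apart. NOD/SHILTJ had 310 and 584 calls, and BXD-40/TyJ 38 and 0.

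Lists of other processes moved in single strains with the preset correlation only. In 129S1/SVIMJ the acute phase list was lower (1 of 24 positive, median −0.42, camera adjusted p = 4.3e-14, and 0.351 with an estimated correlation). TCDD replicate 1 of 129S1/SVIMJ differed from the other TCDD libraries by 119 and 120 times counting error. Those differed from each other by 28.9 times, and this list was not tested without replicate 1. The PPARA targets of fatty acid oxidation were lower in BALB/CJ (0 of 28 positive, 1.7e-10, 0.299) and higher in BXD100/RwwJ (28 of 28 positive, 6.5e-07, 0.326). In CC019/TauUnc the Kupffer list was higher (15 of 16 positive, median 0.84, 1.5e-13, 0.0902), as were the female-biased list (17 of 19, 4.6e-09, 0.321) and the interferon list (22 of 24, 8.3e-09, 0.321). Vehicle replicate 1 of CC019/TauUnc differed from the other vehicle libraries by 98.4 and 106 times counting error. Those differed from each other by 21.1 times, and these lists were not tested without replicate 1. Without the 3 libraries that stood apart the female-biased list of CC019/TauUnc had 0.0448 with an estimated correlation. Over 420 tests of strain and list, A/J had 15 lists called, C57BL6/J and BXD91/2RwwJ 13 each, and DBA1/J 1. With an estimated correlation these numbers were 2, 2, 4 and 0.

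Each strain was then tested against the mean response of the other 13. Cyp1a1 set strains apart: its change exceeded that of the others by 7.13 ± 1.15 in C57BL6/J (adjusted p = 5.0e-04, edgeR), 6.60 ± 1.05 in BXD91/2RwwJ (7.7e-04), 5.46 ± 0.99 in BXD100/RwwJ (0.0156) and 5.33 ± 0.99 in CBA/J (0.0213). The call of BXD100/RwwJ ended without any of its vehicle libraries and that of CBA/J without vehicle replicate 1 or 2. Slc46a3 rose more in BXD91/2RwwJ by 1.64 ± 0.31 (0.00998), a call that ended without vehicle replicate 1 or 3. The change of Cyp1a2 in NOD/SHILTJ lay below the others by −1.82 (0.0338; chosen after its value was seen). In NZO/HILTJ Cyp1a1 and Cyp1a2 lay below the others by −5.79 ± 1.22 and −2.15 ± 0.47 and in CC019/TauUnc Cyp1a2 by −2.13 ± 0.46, with adjusted p of 0.163, 0.163 and 0.348. Without the library labelled C57BL6/J TCDD replicate 3, A/J vehicle replicate 2 and BXD-40/TyJ vehicle replicate 1 these were called, at 4.9e-04, 0.00104 and 0.00222. Slc46a3 in 129S1/SVIMJ then lay lower by −1.30 (6.8e-04), against −1.26 ± 0.30 (0.756) with all libraries.

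Counts against the other strains were largest in 4 strains whose counts moved widely with single libraries. NOD/SHILTJ had 236 calls, 108 of them higher and led by the phosphatase gene Ppp1cc (−1.27 ± 0.19, adjusted p = 9.0e-05, edgeR) and the mitochondrial ribosome gene Mrpl48 (−0.95 ± 0.16, 9.3e-04), with 1 call without vehicle replicate 2 and 445 without TCDD replicate 1. A/J had 48 (4 higher, 44 lower), led by the muscle genes Tpm1 (−1.60 ± 0.28, 0.00483) and Slc25a4 (−3.21 ± 0.58, 0.00564), with 16 without vehicle replicate 2, 0 without TCDD replicate 1 and 84 without vehicle replicate 1. BXD-40/TyJ had 42 (34 higher, 8 lower), led by Myo15b (4.18 ± 0.81, 0.0153) and Smg5 (0.94 ± 0.18, 0.0153), with 0 without vehicle replicate 1 and 84 without TCDD replicate 2. C57BL6/J had 21, led by Mup20 (6.53 ± 1.00, 2.9e-04), with 3 without the library labelled TCDD replicate 3, 2 without vehicle replicate 3 and 393 without TCDD replicate 2. CBA/J and BXD100/RwwJ had 1 each and BXD91/2RwwJ 2, all named above. The other 7 strains had 0 calls in edgeR, with 288 (DBA1/J) to 748 (CC019/TauUnc) genes at an unadjusted p below 0.05 and 1 (DBA1/J) to 11 (CC019/TauUnc) calls by DESeq2. Their smallest p-values, adjusted, were Exo5 and Spsb1 in DBA1/J (both 1), Rbm20 and Rad54l2 in FVB/NJ (both 0.223), Cyp1a1 (0.300) and Tmem97 (0.464) in C3HeB/FeJ, Vnn3 (0.540) and Atf4 (0.867) in BALB/CJ, Nrg4 (0.756) in 129S1/SVIMJ and Rgs10 (0.348) in CC019/TauUnc, beside those given above.

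In the vehicle groups 7579 genes differed between strains, 8735 at an unadjusted p below 0.05. Gstp1 (adjusted p = 2.9e-11, edgeR), Nqo1 (4.4e-06), Htatip2 (8.8e-05), Slc46a3 (0.00770) and Nptx1 (0.0284) differed before any dose. Ahr (0.0626), Cyp1a2 (0.479) and Cyp1a1 (0.844) were not called. Vehicle levels of Ahr ran from a mean log2 CPM of 3.76 in CBA/J to 4.95 in BXD100/RwwJ. The share of reads with more than 1 alignment was 3.74% to 4.35% in the BXD lines and 7.80% to 10.2% in the other strains, so strain and alignment are not separated here, and the effect of alignment on these differences was not tested. Without the BXD lines and CC019/TauUnc 6087 genes differed.

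Of 5 relations across strains none passed. Within the 9 strains in which Cyp1a1 changed less, the vehicle level of Ahr and the Cyp1a1 change had r = −0.585 (permutation p = 0.0946, adjusted 0.473) and rho = −0.533 (permutation p = 0.147); the 5 strains with the largest change formed a cluster too small to test. Vehicle Ahr and the mean change of the AHR battery over 14 strains had r = −0.126 (permutation p = 0.669, adjusted 0.841), rho = −0.0725 (0.809), and r = 0.0097 without CBA/J and BXD100/RwwJ. The Cyp1a1 change and the number of genes called had r = −0.205 (permutation p = 0.695, adjusted 0.841) and rho = 0.341 (0.366) within those 9 strains. The lowest library total and the number called had r = 0.063 (permutation p = 0.841, adjusted 0.841), rho = −0.0757 (0.795), and r = 0.202 without C57BL6/J and FVB/NJ. The spread within groups and the number called had r = 0.214 (permutation p = 0.613, adjusted 0.841) and rho = −0.0891 (0.783) within 12 strains.

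Few calls were shared between strains. Of 491 genes called in any strain 479 were called in 1. Cyp1a2 was called in 8 strains, Cyp1a1 in 6, Htatip2 in 5 and Nptx1 in 4, and the other 8 in 2 each: Slc46a3, Fbxw9, Gstp1, Cyp21a1, Star, Uqcrfs1, Kcnk3 and Adnp, chosen after their values were seen. Adnp, of chromatin regulation, went up in C57BL6/J (1.86) and down in NOD/SHILTJ (−1.61). BXD100/RwwJ and BXD91/2RwwJ shared 5 rising genes where independent lists would share 0.0028, and A/J and BXD-40/TyJ shared 3 falling genes where independent lists would share 0.0548. These were Cyp21a1, Star and Kcnk3, all among the adrenal cortex markers, whose sums stood high in the vehicle libraries described above. Without the 3 libraries that stood apart Star changed by 0.33 and Cyp21a1 by 0.29 in BXD-40/TyJ, so this overlap is not evidence of a shared response to TCDD. BXD-40/TyJ then had 0 calls and could share none, which by itself tests nothing. At an adjusted p below 0.01, 5 genes were shared by at least 2 strains. Most genes called in 1 strain came from NOD/SHILTJ (310 calls), A/J (80), C57BL6/J (65) and BXD-40/TyJ (38), whose counts moved widely with single libraries. All 5 calls of BXD100/RwwJ and the single calls of FVB/NJ and BALB/CJ were shared. In simulated counts 4.48% of 1.5-fold and 41.8% of 2-fold changes in NOD/SHILTJ were called. Few shared calls therefore do not show that the response is particular to each strain.

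The authors' table of fold changes and p-values ordered genes as the count files do. Over 16195 genes the rank correlation of its log2 changes with those computed here was 0.9992 to 0.9999 per strain, across genes, which are not independent replicates. At an adjusted p below 0.05 that table called 716 genes in NOD/SHILTJ, 1.7e+02 in C57BL6/J, 86 in A/J, 83 in BXD-40/TyJ and 3 to 23 in the other strains. Of the calls made here 308 of 310 in NOD/SHILTJ, 64 of 65 in C57BL6/J, 65 of 80 in A/J and 36 of 38 in BXD-40/TyJ were called there too, with the same signs.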

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

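Chosen after the results were seen were the 3 tests of the library labelled C57BL6/J TCDD replicate 3, the test of RNA from other tissues, the test of AHR activation in NOD/SHILTJ, the splits without C3HeB/FeJ and the fits with trends on GC content and gene length taken out. The look at the C3HeB/FeJ libraries followed from the splits. The test of a fall caused by TCDD, the single-library test and the other splits were set before.

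The library labelled C57BL6/J TCDD replicate 3 held 128.5 CPM of Y-linked genes, a signal outside the genes tested, and little Cyp1a1. A male liver under this label may be the source: Xist stood at 0.219 CPM, and a male of the treated group or of another source would both give this value. A swap with a vehicle library of the strain is argued against, since the highest vehicle Cyp1a1 was 0.436 CPM and no vehicle library lacked Xist. A pregnant female that did not respond is argued against, since Xist was 0.212% of the lowest other C57BL6/J library. In this library Cyp1a1 stood at 1.21 CPM and Cyp1a2 at 479 CPM. The other TCDD libraries of C57BL6/J had 1604 and 1393 CPM of Cyp1a1 and 7642 and 8946 CPM of Cyp1a2. The vehicle libraries of the strain averaged 0.293 CPM of Cyp1a1 and 552 CPM of Cyp1a2. The strain of this mouse was not tested, so whether the mouse was dosed stays open.

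Most falling calls of A/J and BXD-40/TyJ rest on A/J vehicle replicate 2, which held 685 CPM of Acta1, 334 of Ckm and 142.4 of Star, and BXD-40/TyJ vehicle replicate 1, which held 210 CPM of Star. RNA of muscle, adrenal and pancreas in these livers may have made most of their size, since without the library of their strain the 86 falling calls kept a median of 13.3% of their log2 fall. In A/J the median of −4.58 became −0.43 without vehicle replicate 2, and −4.41 to −5.11 without any other library. In BXD-40/TyJ the median of −3.35 became −0.46 without vehicle replicate 1, and −3.22 to −3.85 without any other. At least 50% of the log2 fall stayed without that library in 16 of 74 calls of A/J and 3 of 12 of BXD-40/TyJ. Without A/J vehicle replicate 3 it stayed in 66 of the 74. Genes called because a library is high also shrink without it by selection, so the marker genes carry the naming of the tissues. An earlier test, in which 11 of the 86 stayed called without the 3 libraries that stood apart, is not used, because leaving out other libraries ended calls as well. Whether TCDD lowered some of these genes in the liver cannot be told. The other vehicle libraries both lay above all 3 TCDD libraries for 27.9% of the calls. Chance gives 10% only for genes not chosen on these values. These genes were called on the same libraries, which raises the chance share by an unknown amount, so no conclusion is drawn from this test. In A/J the interferon gene Gbp2 (−2.99) was lower without the 3 libraries that stood apart, and it is not among the muscle, adrenal or pancreas markers. Lars2 (−3.50) and Rn7sk (−4.55) fell beside it, and whether RNA or library quality differed between these libraries was not tested. With all libraries the falls were smaller (Gbp2 −2.47, Lars2 −2.94, Rn7sk −3.96). Whether they rest on a single remaining A/J vehicle library was not tested, so no conclusion is drawn from them.

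NOD/SHILTJ had 310 calls. Trends on GC content and gene length may account for part of them: with these taken out 166 were called, 114 of them among the 310, and whether the trends come from the libraries or the livers cannot be told apart. For a single library as the source, the rule set before asked only for a low count without 1 library. Leaving out vehicle replicate 2 left 2 calls, but TCDD replicate 2 left 9, vehicle replicate 3 left 11 and TCDD replicate 3 left 51. Without vehicle replicate 1 there were 431 and without TCDD replicate 1 there were 588. The loss therefore singles out no library. Fewer libraries also lower the power to call, so this test cannot decide on a single source. AHR activation is not settled either, since the upper 95% limit of the Cyp1a2 log2 change was 1.47 around a value of 0.60, which leaves room for a weak response.

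The strain by treatment test itself singled out Cyp1a1 (adjusted p = 8.7e-11), Cyp1a2 (3.4e-06), Slc46a3 (8.2e-04), Nptx1 (0.0126) and Gstp1 (0.0337). A difference of a strain's response from the mean of the other 13, as log2, was called for Tpm1 (−1.60) and Slc25a4 (−3.21) in A/J, Mup20 (6.53) and Cyp1a1 (7.13) in C57BL6/J, Cyp1a1 in CBA/J (5.33), BXD100/RwwJ (5.46) and BXD91/2RwwJ (6.60), Slc46a3 (1.64) in BXD91/2RwwJ, Ppp1cc (−1.27) and Mrpl48 (−0.95) in NOD/SHILTJ, and Myo15b (4.18) and Smg5 (0.94) in BXD-40/TyJ. The number of genes called in such tests was 48 in A/J, 21 in C57BL6/J, 1 in CBA/J, 1 in BXD100/RwwJ, 236 in NOD/SHILTJ, 2 in BXD91/2RwwJ and 42 in BXD-40/TyJ. Without the 3 libraries that stood apart the calls of Tpm1, Slc25a4, Mup20, Myo15b and Smg5 ended. They are therefore not evidence of a strain's response to TCDD. The calls of Cyp1a1 in those strains and of Slc46a3 in BXD91/2RwwJ stayed.

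Other splits of the libraries set these counts in context. Over 25 drawn splits, the real one included, chance could not be excluded for the average (2 splits with as many, real 29, highest other 1490), the strain by treatment test (3 splits, 5, 1182), the calls against the other 13 (6 splits, 351, 5664) and the gene lists (11 splits, 7, 14), while it could for the vehicle differences (1 split, 7579, 679). The splits compare counts of calls and do not test single genes such as Cyp1a1 or Cyp1a2. Apart from the draw with 1490 calls, the other draws for the average gave 0 to 3. Apart from draws with 491 and 1182, those for the strain by treatment test gave 0 to 3 too. The draws with high counts point to a structure of the samples in C3HeB/FeJ. There vehicle replicates 1 and 3 with TCDD replicate 2, against the other 3 libraries, gave 5436 calls of 13929 genes. With trends on GC content and length taken out it was 3838. In the first 3 libraries Malat1, a nuclear RNA, stood at 662, 587 and 809 CPM, against 53.3 to 184 in the others. Without C3HeB/FeJ the average had 23 calls against a highest other of 3, and the strain by treatment test 10 against 3, with 1 of 25 splits as high in each. That strain was left out because its splits had given the high counts, so this does not exclude chance.

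Within a strain the 6 libraries allow 10 splits, too few for a share under 0.05. Fitted alone, the real split and the highest other gave 9 and 1 calls in A/J, 14 and 3 in CBA/J, 3 and 2 in FVB/NJ, 5 and 2 in BALB/CJ, 24 and 0 in NOD/SHILTJ and 10 and 0 in BXD-40/TyJ (1 split with as many each). They gave 5 and 30 in BXD100/RwwJ and 6 and 11 in BXD91/2RwwJ (2 splits with as many each). They gave 0 and 0 in C57BL6/J and 129S1/SVIMJ, 0 and 3 in DBA1/J, 0 and 5436 in C3HeB/FeJ, 0 and 2 in NZO/HILTJ and 0 and 1 in CC019/TauUnc, where all 10 splits had as many.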

How the results depend on the processing

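Chosen after the data were seen were the fits without the library labelled C57BL6/J TCDD replicate 3 (here the male-marker library), without it, A/J vehicle replicate 2 and BXD-40/TyJ vehicle replicate 1 (here the 3 libraries), and with trends on GC content and gene length taken out. No paired analysis was possible because replicate numbers follow only the order of accessions and the labels tie no TCDD mouse to a vehicle mouse. Where no cause is given, the cause was not tested.

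The average effect (29 calls) stayed within 1.5 times under the other alternatives and fell to 5 without the BXD lines and CC019/TauUnc; it ran from 23 to 33 leaving out single libraries and from 9 (BXD91/2RwwJ) to 31 (FVB/NJ) leaving out strains. The strain by treatment test (5) gave 166 with DESeq2, 11 without the male-marker library, 14 without the 3 libraries, 15 with the GC and length trends taken out and 1 without the BXD lines and CC019/TauUnc; it ran from 4 to 16 leaving out libraries and from 2 (BXD91/2RwwJ) to 10 (C3HeB/FeJ) leaving out strains. The vehicle differences (7579) ran from 6759 to 8216 leaving out single libraries, and were 6087 without the BXD lines and CC019/TauUnc. Of the 7 gene lists called, 3 stayed with an estimated correlation and 3 with fry, and leaving out libraries gave 6 to 8. Of 12 genes shared between strains, 5 were left at an adjusted p below 0.01. None of the 5 relations passed under any setting.

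Within strains (518 calls in all) DESeq2 gave 1188, no filter 228 and each strain fitted alone 76. DESeq2 gave 1.8e+02 in C57BL6/J (65), 19 in CBA/J (4), 2 in DBA1/J (0), 14 in BXD100/RwwJ (5), 6 in FVB/NJ (1), 17 in C3HeB/FeJ (5), 6 in BALB/CJ (1), 2 in NZO/HILTJ (0), 737 in NOD/SHILTJ (310), 21 in BXD91/2RwwJ (9), 4 in 129S1/SVIMJ (0), 89 in BXD-40/TyJ (38) and 4 in CC019/TauUnc (0). No filter gave 31 in C57BL6/J, 0 in FVB/NJ and BALB/CJ, 3 in C3HeB/FeJ, 109 in NOD/SHILTJ and 15 in BXD-40/TyJ, where more genes were tested. Without the male-marker library C57BL6/J had 10, FVB/NJ 2, BALB/CJ 2 and NOD/SHILTJ 600. Without the 3 libraries A/J (80) had 28, C57BL6/J 13, FVB/NJ 2, BALB/CJ 2, NOD/SHILTJ 584 and BXD-40/TyJ 0. With GC and length trends taken out C57BL6/J had 99, C3HeB/FeJ 3, NOD/SHILTJ 166 and BXD-40/TyJ 21. Fitted alone, A/J had 9, C57BL6/J 0, CBA/J 14, FVB/NJ 3, C3HeB/FeJ 0, BALB/CJ 5, NOD/SHILTJ 24 and BXD-40/TyJ 10.

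Against the other 13 (351 calls in all) no filter gave 1.4e+02, the fit without the male-marker library 705 and that without the 3 libraries 627. No filter gave 66 in NOD/SHILTJ (236) and 13 in BXD-40/TyJ (42). Without the male-marker library C57BL6/J (21) had 3, CBA/J (1) 2, BXD100/RwwJ (1) 3, C3HeB/FeJ (0) 1, NZO/HILTJ (0) 2, NOD/SHILTJ 584, BXD91/2RwwJ (2) 5, 129S1/SVIMJ (0) 1 and CC019/TauUnc (0) 3. Without the 3 libraries A/J (48) had 17, C57BL6/J 1, CBA/J 2, BXD100/RwwJ 3, C3HeB/FeJ 1, NZO/HILTJ 2, NOD/SHILTJ 593, BXD91/2RwwJ 4, 129S1/SVIMJ 1, BXD-40/TyJ 0 and CC019/TauUnc 3. With GC and length trends taken out C57BL6/J had 48, NOD/SHILTJ 1.3e+02 and BXD-40/TyJ 23. DESeq2, run beside these tests, gave 78 in A/J, 114 in C57BL6/J, 10 in CBA/J, 8 in BXD100/RwwJ, 567 in NOD/SHILTJ, 14 in BXD91/2RwwJ and 94 in BXD-40/TyJ. In the strains with 0 in edgeR it gave 1 in DBA1/J, 9 in FVB/NJ, 7 in C3HeB/FeJ, 5 in BALB/CJ, 3 in NZO/HILTJ and 129S1/SVIMJ and 11 in CC019/TauUnc. Median-ratio size factors gave CBA/J 2, and dispersion without robust estimation gave BXD91/2RwwJ 4.

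Leaving out single libraries, the lowest and highest counts within strains were 2 and 1.6e+02 in A/J, 7 and 552 in C57BL6/J, 2 and 28 in CBA/J, 2 and 5 in BXD100/RwwJ, 0 and 1 in FVB/NJ and BALB/CJ, 2 and 706 in C3HeB/FeJ, 2 and 588 in NOD/SHILTJ, 5 and 9 in BXD91/2RwwJ, 0 and 8 in 129S1/SVIMJ, 0 and 72 in BXD-40/TyJ, and 0 throughout in DBA1/J, NZO/HILTJ and CC019/TauUnc. Against the other 13 they were 0 and 84 in A/J, 2 and 393 in C57BL6/J, 0 and 21 in CBA/J, 0 and 2 in BXD100/RwwJ, 0 and 318 in C3HeB/FeJ, 1 and 445 in NOD/SHILTJ, 1 and 4 in BXD91/2RwwJ, 0 and 84 in BXD-40/TyJ, and 0 throughout in the other 6 strains.

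Of 240 results for named genes, 211 kept direction and side of the threshold with DESeq2 and 23 passed newly. With median-ratio size factors 1 passed newly, without the filter 14 no longer passed, with GC and length trends taken out 9 passed newly and 6 no longer passed, without the male-marker library 17 and 7, and without the 3 libraries 16 and 15. Leaving out single libraries, 50 to 64 of the named genes passed. In 2 results the direction reversed without the 3 libraries, which take out the high vehicle library: Cyp21a1 in BXD-40/TyJ to 0.29 and Star in BXD-40/TyJ to 0.33. The change of Mybpc1 in A/J was lost there, at 0, which has no direction. Leaving out single libraries, Mybpc1 ranged from −11.98 to 0, Cyp21a1 from −10.42 to 0.28 and Star from −5.95 to 0.32. Depth limits Cyp1a1 in vehicle, at 0.0593 to 2.43 CPM in libraries of at least 9122410 counts.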

Other observations

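The test of the clock genes was chosen after the result was seen. Genes of the daily clock differed widely between libraries of the same group. Arntl, which encodes the clock activator BMAL, ran from 0.219 to 29.1 CPM and Dbp, a clock output gene that peaks at the opposite time of day, from 3.75 to 502 CPM. Taken as deviations from the group means over 84 libraries, Arntl and Dbp moved against each other with r = −0.829 (permutation p = 1e-05, the smallest that 100000 permutations can give) and rho = −0.814 (1e-05), and r was −0.769 without the 2 farthest libraries. A candidate explanation is that the hour of tissue collection differed between libraries, since the correlation of −0.829 has the sign that a shift of clock phase gives; the labels state no hour.

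Alongside these, C3HeB/FeJ livers fell into the sets described above by Xist too, at 461, 505 and 679 CPM in vehicle replicates 1 and 3 and TCDD replicate 2, and at 52.0 to 146.5 CPM in the others. Skeletal muscle markers also stood at 555 CPM in BXD91/2RwwJ TCDD replicate 2, 166 in CBA/J vehicle replicate 3 and 214 in CBA/J TCDD replicate 2. The cholangiocyte keratin Krt19 stood at 33.8 CPM in 129S1/SVIMJ TCDD replicate 1, 25.8 and 13.9 in BXD-40/TyJ TCDD replicates 2 and 3, 21.2 in NOD/SHILTJ vehicle replicate 3, 18.3 in BXD91/2RwwJ vehicle replicate 3 and 15.1 in BALB/CJ vehicle replicate 2, with a low of 0.0524 among all libraries. The pancreas gene Ctrb1 stood at 4.34, 13.3, 5.66, 3.83, 9.37 and 0.116 CPM in these libraries in the same order. Whether a varying share of duct or pancreas cells moved epithelial genes such as Ctse and Krt4 in NOD/SHILTJ was not tested. The same question for the rises of Fcgbp and Myo15b in BXD-40/TyJ was not tested either. Those rises also stand beside the trend on GC content that ran with the treatment in that strain.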
